A study of Mus musculus with 12 samples.

How the data were processed

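RNA from the IMCD3 subclone 53a was made into poly(A) libraries with a TruSeq kit, per the labels' protocols. Per the labels, 12 libraries form 4 groups of 3, vehicle or mifepristone with or without 100 mM added NaCl. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so limma p-values measure the spread between these libraries, which may be technical. The deposited expression table names its columns Control or by the mutant, with NaCl where it applies and a letter. The 6 Control columns match the titles by name. The 6 mutant columns were matched to the mifepristone titles by the NaCl part, by the letter and by knowledge of the study, in which mifepristone induces a dominant-negative transcription factor in this subclone. The number of columns left without a sample was 0.

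Reads were processed by the authors with Trimmomatic 0.32, STAR 2.4.2a, SAMtools 1.0 and DESeq2 1.12.3 on GRCm38 (mm10), per the submitters' processing notes, which give no role or order. The counting program, the annotation and whether strand was used are not given in the sources used here, so overlapping and antisense genes may share reads. The authors deposited FPKM values per library for 48034 genes. The authors' deposited comparison tables hold a mean signal per gene over all 12 libraries (normalized counts, per the file headers), log2 fold changes, and adjusted p-values, per the file headers. They also hold a true or false mark of a nearby ChIP peak. In the authors' deposited mifepristone table the smallest absolute log2 fold change with an adjusted p-value below 1 was 1.07, and for their interaction it was 1.21, so these p-values may test a minimum fold change.

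Each FPKM value times the ratio of the authors' mean signal to the gene's mean FPKM gave a normalized value, and division by 1 step per library gave whole reads for 100.0% of values in each library, within a tolerance of 0.05. These recovered reads summed to between 41940955 and 49270776 per library, and 3 reads, the limit that a count of 0 allows, equal a floor of 0.061 to 0.072 counts per 1e+06 reads (CPM). Counting intervals cover counting error only.

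The main test was limma 3.58.1 (R 4.3.3) with trended, robust empirical Bayes on log2(FPKM + 0.5), with the 4 group means over all 12 libraries and 8 residual degrees of freedom. Fold changes are on this scale, which understates the change of genes near 0. Genes with an FPKM of at least 1 in at least 3 libraries were tested (14044), and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. The contrasts were mifepristone against vehicle without and with NaCl, NaCl against none in vehicle and in mifepristone cells, and the interaction. A set of 29 gene lists (pathways, tubule cell types and other cell types) was tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The 23 lists with at least 5 measured members entered. Nearby peaks were compared by Fisher's exact test (two-sided), adjusted over 16 tests. Coordinates and exon lengths come from GENCODE release M21 on GRCm38, to which 98.5% of gene identifiers matched.

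Genes were named by a rule fixed before the data were examined, as were the lists, tests and most alternatives. The rule takes 15 genes always, the 8 largest rises and 8 largest falls per comparison (5 and 5 for the interaction) among called genes with a mean FPKM of at least 1 and non-overlapping groups, up to 4 members per list by smallest adjusted p, and the 5 largest rises and falls among genes marked with a peak. Genes without a proper symbol were left out, and some list members were dropped for length. Results for some genes that the rule names are not reported here.

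In data simulated for the mifepristone comparison without NaCl over 13625 genes, the same fit recovered 86.6% of genes changed 1.5-fold (58 of 67). It recovered 97.0% of those changed 2-fold (64 of 66) and 100.0% of those changed 4-fold (64 of 64), with 17 calls among 13428 unchanged genes. Only genes with many reads were changed, genes were drawn independently, and no library had a length trend. The simulation thus does not give the error of calls where most genes change and libraries differ by length trends. Alternatives were other pseudocounts, filters, scalings, a replicate block, library weights, a stricter threshold, leaving out each library, and 3 chosen after seeing the data, namely voom on the recovered reads, values corrected for length trends within groups, and leaving out vehicle A and mifepristone C together. The length correction leaves group means and fold changes as they were and narrows only the spread within groups. A lower adjusted p with it follows from its construction and does not test a trend between groups. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, intervals with scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.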

Results

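RNA was sequenced from IMCD3 cells, a mouse cell line derived from the inner medullary collecting duct, in its subclone 53a. In this subclone mifepristone switches on a dominant-negative mutant of a transcription factor of kidney tubule epithelium, as known of the study. Cells received vehicle or mifepristone, each without or with 100 mM added NaCl, which makes 4 groups of 3 libraries (A, B and C) and 12 libraries in all. The reads recovered from the deposited gene values summed to between 41940955 and 49270776 per library, without reads not assigned to a gene. A total of 14044 genes reached an FPKM of at least 1 in at least 3 of the 12 libraries and were tested. The first principal component took 49.6% of the variance and the next 36.1%, and the 12 libraries fell into their 4 groups on these axes. Correlations of log2 values ran from 0.9893 to 0.9973 within a group and from 0.9207 to 0.9683 between groups. Vehicle A and mifepristone C deviated from their group mean along transcript length, with shorter transcripts higher (Spearman rho across genes of -0.44 and -0.51 between deviation and exon length). The trend was not particular to them, since the other libraries ran from -0.29 to 0.46, the highest being mifepristone A, and deviations from a shared mean oppose each other.

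Hnf4a, a transcription factor of liver and proximal tubule, and Aqp2, the vasopressin-regulated water channel, lay below the expression filter, with 0 to 6 reads per library.

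**Figure D1:**
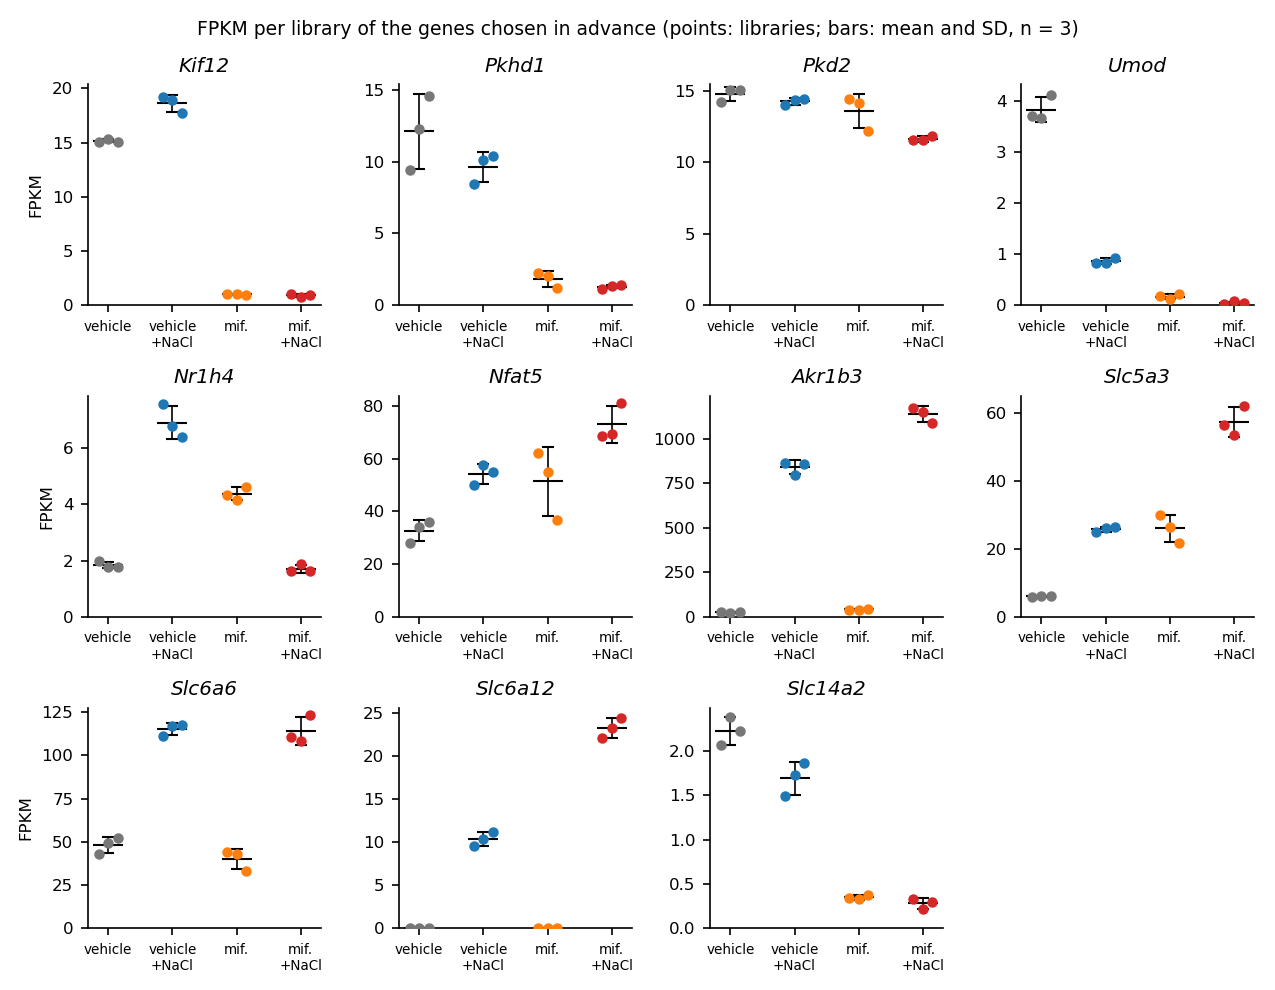
FPKM (vertical axes, each from 0) of 11 genes chosen in advance in the 4 groups of 3 libraries. Points are libraries, and bars give the mean and SD (n = 3). Kif12, Pkhd1 and Slc14a2 are low in both mifepristone groups, Akr1b3 and Slc6a12 are high in both NaCl groups, and Nr1h4 is higher with NaCl in vehicle cells and lower with NaCl in mifepristone cells.

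Mifepristone was compared with vehicle without NaCl to ask which genes change when the mutant is switched on. No cells without the inducible mutant are among the 12 libraries, so an action of mifepristone itself is not separated from that of the mutant. Kif12, a kinesin of the primary cilium, fell 10.4-fold (log2 fold change -3.38, SE 0.059, n = 3 per group), from 15.2 ± 0.17 to 1.01 ± 0.0271 FPKM (SD). Pkhd1, the gene of autosomal recessive polycystic kidney disease, fell 5.4-fold (-2.43, SE 0.184), Umod, which encodes uromodulin, fell 6.46-fold (-2.69, SE 0.078), and the urea transporter gene Slc14a2 fell 3.21-fold (-1.68, SE 0.082). Slc5a3, which imports myo-inositol, rose 4.06-fold (2.02, SE 0.092), and Nr1h4, the bile acid receptor FXR, rose 2.08-fold (1.06, SE 0.071). In all, limma called 8391 of the 14044 genes at an adjusted p under 0.05, 3970 higher and 4421 lower, and 574 of the higher and 327 of the lower genes changed at least 2-fold. Median-ratio scaling gave 4161 higher and 4291 lower. With voom on the recovered reads, which adds less to low values, the log2 fold changes of Umod and Slc14a2 were -4.50 and -2.67.

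The 8 largest falls of the comparison without NaCl were those of Cdkl1, a cilium-associated kinase gene (10.5-fold), Kif12, the tetraspanin gene Tspan8 (10.1-fold), the kidney cadherin gene Cdh6 (9.95-fold), the sulfotransferase gene Sult1c2 (9.19-fold), the phosphodiesterase gene Pde4c (8.96-fold), Cbs, the first enzyme of transsulfuration (8.75-fold), and Efhd1 (8.35-fold). Each of these 8 genes carried the authors' mark of a nearby ChIP peak. Their ranking holds for the scale of the main test, which understates the change of genes with low FPKM. Umod, which lacked the mark, fell from a mean of 3.84 to 0.172 FPKM. Its log2 fold change was -2.69 on that scale and -4.50 with voom on the recovered reads. A ranking by voom is not given here, so the shared mark may depend on the scale. The 8 largest rises were led by Sohlh1, a germ-cell transcription factor gene, which had 1 read in the 3 vehicle libraries together and 8720 in the 3 mifepristone libraries (ratio after scaling to library depth 8340, 95% exact counting interval 1500 to 329000). Sohlh1 reached 47.4 ± 6.85 FPKM (SD, n = 3). Slpi, a secreted protease inhibitor gene, rose 53.8-fold (log2 fold change 5.75, SE 0.108), the glutathione transferase gene Gstm7 41.5-fold (5.37, SE 0.084), and Ass1, an enzyme of arginine synthesis, 23.6-fold (4.56, SE 0.074). The acute-phase gene Saa3 had 1 read in the vehicle libraries together and 720 in the mifepristone libraries (ratio 688, interval 123 to 27200). Prune2 rose 19.0-fold, the sulfotransferase gene Chst1 17.9-fold and the interferon-induced gene Ifi27l2a 14.7-fold. Of the genes named in advance, Akr1b3, the sorbitol-forming aldose reductase, rose 1.6-fold (0.68, SE 0.083), and Nfat5, the transcription factor of the hypertonic response, rose 1.54-fold (0.62, SE 0.165). Pkd2 (-0.12, SE 0.054) and the betaine transporter gene Slc6a12 (0.04, SE 0.06) did not pass the test. Without mifepristone A the value of Pkd2 was -0.16 and passed (limma adjusted p = 0.0293), and it also passed under quantile normalization (-0.15). With length-corrected values it passed at an unchanged -0.12 (limma adjusted p 0.000789), because that correction narrows only the spread within groups. The taurine transporter gene Slc6a6 (-0.27, SE 0.104) had a limma adjusted p of 0.0452, but the call was lost without vehicle B (adjusted p 0.112), vehicle C (0.149), vehicle plus NaCl A (0.0571), B or C (0.0595 each), mifepristone C (0.135), or mifepristone plus NaCl A (0.0581) or B (0.0558), and under other settings (0.0704 to 0.12). The Slc6a6 log2 fold change itself was -0.14 without mifepristone C and -0.21 without vehicle C.

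Genes of cholesterol synthesis fell together with mifepristone in cells without NaCl. Of 24 measured members, 22 fell and 0 rose, and the same 22 and 0 were called when adjusted over the list alone. The median log2 fold change was -0.95 (camera adjusted p = 2.74e-11, and adjusted p = 0.0189 with an estimated correlation). Hmgcs1 fell 2.87-fold (-1.52, SE 0.049), Mvd 2.44-fold (-1.29, SE 0.036) and Insig1 2.11-fold. Among 18 measured genes that earlier studies tied to the mutated factor in kidney, 13 fell and 2 rose, 13 and 2 when adjusted over the list alone (median -0.67, camera adjusted p = 0.000419, and adjusted p = 0.035 with an estimated correlation). Besides Kif12 these included the cilium gene Cys1 (5.63-fold lower) and the potassium channel gene Kcnj16 (3.41-fold lower), while Socs3, an inhibitor of cytokine signalling, rose 4.73-fold. Of 28 primary cilium genes 20 fell and 4 rose, 21 and 4 when adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.000419). That call was lost at adjusted p = 0.0831 with an estimated correlation. Ift88 (1.59-fold) and Ift57 (1.68-fold), genes of intraflagellar transport, were among those that fell, and Bbs2 rose 1.43-fold.

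Interferon response genes rose in 21 of 22 cases without NaCl and fell in 1, 21 and 1 when adjusted over the list alone (median 0.75, camera adjusted p = 1.42e-07). The list was not called with an estimated correlation (adjusted p = 0.323 with an estimated correlation). Gbp2 rose 3.33-fold, Oasl2 2.32-fold and Oas1a 2.15-fold. Of 17 NF-kB and chemokine genes 12 rose and 2 fell, the same when adjusted over the list alone (median 0.41, camera adjusted p = 0.000419, but adjusted p = 0.126 with an estimated correlation). Complement C3 rose 6.5-fold, the NF-kB inhibitor gene Nfkbia 5.68-fold and the chemokine gene Ccl2 5.15-fold. Hypoxia and glycolysis genes fell in 13 of 15 cases and rose in 1, the same when adjusted over the list alone (median -0.55, camera adjusted p = 0.000283, but adjusted p = 0.369 with an estimated correlation). The glucose transporter gene Slc2a1 fell 2.69-fold and hexokinase Hk2 2.56-fold, whereas Vegfa rose 2.14-fold. Mesenchymal and matrix genes fell in 9 of 13 cases and rose in 1, the same when adjusted over the list alone (median -0.54, camera adjusted p = 0.00663, but adjusted p = 0.0831 with an estimated correlation). Cyr61 (4.98-fold) and Ctgf (3.24-fold) fell. Both are also widely known as targets of YAP or TGF-β signalling. Mitosis genes fell in 14 of 21 cases and rose in 0, the same when adjusted over the list alone, by small amounts (median -0.21, Top2a 1.37-fold, camera adjusted p = 0.00283, but adjusted p = 0.0897 with an estimated correlation). Osmotic response genes went both ways, with 8 risen and 4 fallen of 17, 9 and 4 when adjusted over the list alone, and were not called as a list (camera adjusted p = 0.115). The water channel gene Aqp1 fell 6.38-fold.

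With NaCl present, mifepristone lowered Fxyd2, the gamma subunit of Na,K-ATPase, 19.5-fold (log2 fold change -4.28, SE 0.055), from 108.7 ± 4.37 to 5.11 ± 0.103 FPKM (SD, n = 3 per group). The phosphate transporter gene Slc17a1 fell 11.4-fold (-3.52, SE 0.06), the metallothionein gene Mt2 11.7-fold (-3.55, SE 0.113), Cdkl1 14.4-fold, Kif12 13.4-fold, Cdh6 11.5-fold and Sult1c2 9.75-fold. Nr1h4 fell 3.36-fold (-1.75, SE 0.071), whereas it had risen without NaCl. Gstm7 rose 58.5-fold (5.87, SE 0.084), Sohlh1 87.3-fold, the chemokine gene Ccl7 36.0-fold (5.17, SE 0.174) and the surface antigen gene Ly6c1 31.8-fold. In all, limma called 8240 genes, 3766 higher and 4474 lower, of which 583 and 353 changed at least 2-fold. The excess of lower genes depended on scaling, as median-ratio scaling gave 4227 higher and 4049 lower, while quantile normalization kept it with 4065 and 4578.

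Further large rises in the mifepristone comparison with NaCl were Ifi27l2a (21.4-fold), Tmem64 (19.0-fold), the Wnt receptor gene Fzd4 (17.3-fold) and Slpi (15.4-fold). Mir681, with 103 reads in the vehicle plus NaCl libraries together and 1 in the mifepristone plus NaCl libraries (ratio after scaling to library depth 0.00988, 95% exact counting interval 0.000248 to 0.0563), lies inside Cdkl1 on the same strand, and its reads may not be separable from those of Cdkl1. Pkhd1 fell 5.63-fold (-2.49, SE 0.184), Slc14a2 2.8-fold, Umod 2.48-fold and Pkd2 1.21-fold (-0.28, SE 0.054). Slc5a3 rose 2.2-fold, Slc6a12 2.19-fold (1.13, SE 0.06) and Akr1b3 1.36-fold. Slc6a6 did not pass the test (-0.02, SE 0.104). Nfat5 (0.43, SE 0.165) had a limma adjusted p of 0.0439, but the call was lost without vehicle B (adjusted p 0.057) or C (0.0502), vehicle plus NaCl A (0.125), B (0.0624) or C (0.0824), mifepristone B (0.0512), or mifepristone plus NaCl A (0.0638), B (0.0682) or C (0.136), and under other settings (0.0742 to 0.0849). With voom on the recovered reads, which adds less to low values, the log2 fold changes of Umod, Slc14a2, Slpi and Sohlh1 were -4.13, -2.55, 6.04 and 10.58.

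Of the 18 genes tied to the mutated factor by earlier work, 16 fell and 1 rose in the presence of NaCl, 16 and 1 when adjusted over the list alone (median -1.05, camera adjusted p = 5.29e-07, and adjusted p = 0.00894 with an estimated correlation). Cholesterol synthesis genes fell in 22 of 24 cases and rose in 0, the same when adjusted over the list alone (median -0.82, camera adjusted p = 4.8e-09, and adjusted p = 0.019 with an estimated correlation), with Cyp51 2.51-fold and Insig1 2.37-fold lower. Interferon response genes rose in 20 of 22 cases and fell in 1, the same when adjusted over the list alone (median 0.86, camera adjusted p = 5.73e-08, but adjusted p = 0.339 with an estimated correlation), with Irf7 2.55-fold higher. NF-kB and chemokine genes rose in 12 of 17 cases and fell in 2, the same when adjusted over the list alone (median 1.27, camera adjusted p = 7.04e-05, but adjusted p = 0.15 with an estimated correlation), with C3 13.1-fold and Ccl2 5.89-fold higher. Hypoxia and glycolysis genes fell in 12 of 15 cases and rose in 2, the same when adjusted over the list alone (median -0.36, camera adjusted p = 0.00489, but adjusted p = 0.677 with an estimated correlation). Osmotic response genes rose in 11 of 17 cases and fell in 4, the same when adjusted over the list alone (median 0.63, camera adjusted p = 0.0235, but adjusted p = 0.32 with an estimated correlation). The kinase gene Sgk1 rose 2.58-fold and the chaperone gene Hsph1 2.22-fold, while Aqp1 fell 3.07-fold. Primary cilium genes fell in 15 of 28 cases and rose in 3, the same when adjusted over the list alone (median -0.19, camera adjusted p = 0.0235), and mitosis genes fell in 12 of 21 cases and rose in 2, or in 12 and 3 when adjusted over the list alone (median -0.15, camera adjusted p = 0.0334). Both calls were lost at adjusted p = 0.312 with an estimated correlation, and among genes of mean FPKM of at least 5 (camera adjusted p = 0.0976 and 0.0617).

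The mifepristone effects without and with NaCl, which share no library, were correlated across the 14044 genes (Pearson r 0.775, Spearman rho 0.696), though genes are not independent replicates. Both comparisons called 2611 genes higher, against 1065 for independent lists, and 2993 lower, against 1408. Another 419 genes were called in opposite directions, Nr1h4 among them, against 2450 for independent lists.

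**Figure D2:**
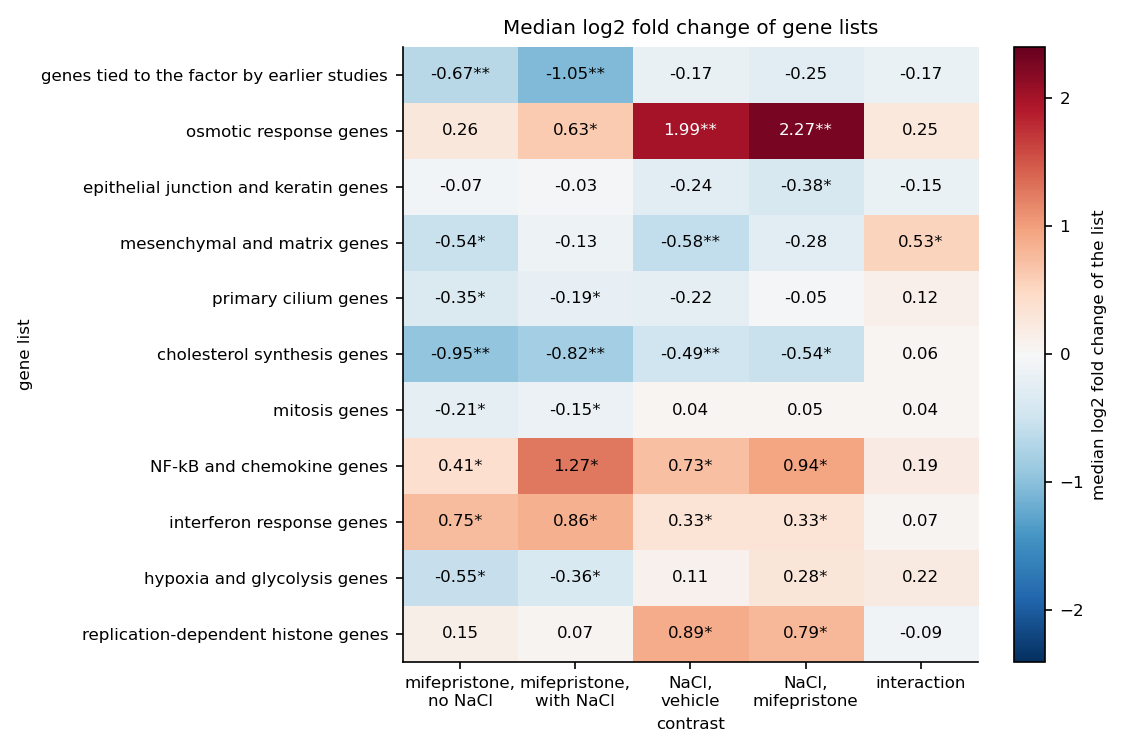
Median log2 fold change (colour and number) of each gene list (vertical axis) that was called in at least 1 contrast (horizontal axis). A star marks a camera adjusted p under 0.05 with the preset correlation, and a second star marks a call that also holds with an estimated correlation. Cholesterol synthesis genes are negative in all 4 treatment contrasts, and osmotic response genes have their largest medians, 1.99 and 2.27, in the NaCl contrasts.

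The hypertonic response was followed by comparing NaCl with no added NaCl in vehicle cells. Akr1b3 rose 32.3-fold (log2 fold change 5.01, SE 0.083), from 25.6 ± 2.11 to 839.9 ± 39.0 FPKM (SD, n = 3 per group), and Slc6a12 rose 21.1-fold (4.40, SE 0.06). Slc5a3 rose 4.04-fold (2.02, SE 0.092), Slc6a6 2.38-fold (1.25, SE 0.104) and Nfat5 1.65-fold (0.72, SE 0.165). Of 17 osmotic response genes 15 rose and 1 fell, 16 and 1 when adjusted over the list alone (median 1.99, camera adjusted p = 1.99e-12, and adjusted p = 0.014 with an estimated correlation). Sgk1 rose 11.6-fold, Aqp1 rose as well (log2 fold change 3.46, SE 0.042), and the near-identical heat shock genes Hspa1a and Hspa1b, whose reads may not be separable, rose 6.09-fold and 6.11-fold. In all, limma called 7965 genes, 3541 higher and 4424 lower, of which 384 and 180 changed at least 2-fold. With median-ratio scaling 3962 were higher and 4112 lower. With a pseudocount of 0.1 or 1 the number at least 2-fold lower was 306 or 115, and with voom it was 398, while Slc6a12 had a log2 fold change of 9.60.

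The largest rises with NaCl in vehicle cells were those of the protease-like gene Prss35 (206.0-fold), Fxyd2 (log2 fold change 7.64, SE 0.055, from 0.0466 ± 0.021 to 108.7 ± 4.37 FPKM, SD, n = 3), Ranbp3l (53.4-fold), Akr1b3, Slc17a1 (29.4-fold), Slc6a12, the organic anion transporter gene Slco4a1 (18.8-fold) and the ubiquitin ligase gene Rnf183 (17.0-fold). The largest falls included those of Lcn2, which encodes lipocalin 2 (5.99-fold), the claudin gene Cldn2 (5.73-fold), Adh7 (5.35-fold), Tspan8 (5.21-fold), Efhd1 (4.84-fold), Stc2 (4.73-fold) and the angiotensinogen gene Agt (4.71-fold). Umod fell 3.19-fold (log2 fold change -1.67, SE 0.078), Slc14a2 1.25-fold (-0.32, SE 0.082), and Nr1h4 rose 3.16-fold (1.66, SE 0.071) and Kif12 1.22-fold. Pkd2 (-0.05, SE 0.054) and Pkhd1 (-0.30, SE 0.184) did not pass the test. Pkd2 (-0.08) and Pkhd1 (-0.46) passed without vehicle A and mifepristone C together and both with library quality weights. Pkhd1 also passed with length-corrected values (limma adjusted p 0.0448), at an unchanged -0.30 and a spread narrowed by the correction. With voom the log2 fold change of Agt was -3.40.

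Cholesterol synthesis genes fell with NaCl in vehicle cells in 19 of 24 cases and rose in 0, 20 and 0 when adjusted over the list alone (median -0.49, camera adjusted p = 1.7e-08, and adjusted p = 0.0255 with an estimated correlation), with Hmgcs1 1.98-fold and Mvd 1.91-fold lower. The mifepristone comparison without NaCl uses the same vehicle libraries, so the falls in the 2 comparisons are not independent. Mesenchymal and matrix genes fell in 10 of 13 cases and rose in 1, the same when adjusted over the list alone (median -0.58, camera adjusted p = 0.00226, and adjusted p = 0.043 with an estimated correlation). Ctgf fell 4.31-fold and Cyr61 2.24-fold, while N-cadherin Cdh2 rose 1.8-fold. NF-kB and chemokine genes rose in 14 of 17 cases and fell in 2, the same when adjusted over the list alone (median 0.73, camera adjusted p = 9.71e-05, but adjusted p = 0.091 with an estimated correlation). Ccl2 rose 7.07-fold and Ccl5 3.72-fold, while Lcn2 and C3 (3.18-fold) fell. Interferon response genes rose in 14 of 22 cases and fell in 0, the same when adjusted over the list alone (median 0.33, camera adjusted p = 0.00263, but adjusted p = 0.893 with an estimated correlation). All 6 measured replication-dependent histone genes rose, also when adjusted over the list alone (median 0.89, camera adjusted p = 0.00543, but adjusted p = 0.091 with an estimated correlation). Their transcripts mostly lack a poly(A) tail, and the libraries were made from poly(A) RNA. Hist1h3c rose 2.45-fold and Hist1h1b 1.96-fold.

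In mifepristone cells NaCl raised Akr1b3 27.3-fold (log2 fold change 4.77, SE 0.083), from 41.4 ± 4.75 to 1139 ± 43.5 FPKM (SD, n = 3 per group), and Slc6a12 44.7-fold (5.48, SE 0.06). Osmotic response genes rose in 16 of 17 cases and fell in 0, the same when adjusted over the list alone (median 2.27, camera adjusted p = 4.19e-13, and adjusted p = 0.0117 with an estimated correlation). Aqp1 rose 22.9-fold, Sgk1 17.1-fold, Hsph1 7.41-fold, Slc6a6 2.84-fold and Slc5a3 2.19-fold. Nr1h4 fell 2.21-fold (-1.15, SE 0.071). In all, limma called 8248 genes, 3440 higher and 4808 lower, of which 468 and 257 changed at least 2-fold. The excess of lower genes was absent with median-ratio scaling, which gave 4028 higher and 4036 lower, but remained under quantile normalization, with 3828 and 4557. With a pseudocount of 0.1 the number at least 2-fold lower was 389, and with voom it was 437, while Slc6a12 had a log2 fold change of 9.45.

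The other large rises with NaCl in mifepristone cells were Prss35 (263.0-fold), Ranbp3l (42.6-fold), the platelet chemokine gene Ppbp (34.1-fold), the lipoxygenase gene Alox12e (28.8-fold) and malic enzyme Me1 (28.4-fold). The largest falls were Fgfbp1 (10.6-fold), the imprinted gene Peg10 (9.57-fold), Lcn2 (9.0-fold), Mgst1 (7.23-fold), Saa3 (6.63-fold), the uroplakin gene Upk1a (6.27-fold), Slpi (5.75-fold) and the metallothionein gene Mt1 (5.31-fold). Pkd2 fell 1.16-fold and Umod 1.22-fold on the scale log2(FPKM + 0.5), from 0.172 ± 0.0558 to 0.0484 ± 0.0253 FPKM (SD, n = 3 per group), and Slc14a2 (-0.12, SE 0.082), Kif12 (-0.08, SE 0.059) and Pkhd1 (-0.36, SE 0.184) did not pass. Kif12 passed without mifepristone plus NaCl A (-0.14, limma adjusted p = 0.0432), and Slc14a2 (-0.25) and Kif12 (-0.17) passed under quantile normalization. Pkhd1 passed without mifepristone C (-0.57, limma adjusted p = 0.00753) and with library quality weights (0.0145). Pkhd1 also passed with length-corrected values (0.0191), at an unchanged -0.36 and a spread narrowed by the correction. With voom the log2 fold changes of Alox12e and Mgst1 were 8.46 and -4.71. Nfat5 rose 1.45-fold (0.53, SE 0.165, limma adjusted p = 0.0169), but the call was lost without mifepristone plus NaCl C (0.46, adjusted p 0.0628), with library quality weights (0.29, 0.0809) and with only the groups of the contrast (0.53, 0.0533). Without mifepristone C the Nfat5 log2 fold change was 0.31.

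Cholesterol synthesis genes fell with NaCl in mifepristone cells in 21 of 24 cases and rose in 3, the same when adjusted over the list alone (median -0.54, camera adjusted p = 2.29e-05, but adjusted p = 0.0641 with an estimated correlation). Epithelial junction and keratin genes fell in 16 of 22 cases and rose in 3, the same when adjusted over the list alone (median -0.38, camera adjusted p = 0.00608, but adjusted p = 0.0641 with an estimated correlation). The claudin genes Cldn8 (3.86-fold) and Cldn3 (3.52-fold) and occludin Ocln (2.26-fold) fell, and kidney cadherin Cdh16 rose 3.79-fold. NF-kB and chemokine genes rose in 13 of 17 cases and fell in 3, the same when adjusted over the list alone (median 0.94, camera adjusted p = 3.05e-05, but adjusted p = 0.0885 with an estimated correlation), with Cxcl2 8.49-fold and Ccl2 8.09-fold higher. Interferon response genes rose in 15 of 22 cases and fell in 3, 17 and 3 when adjusted over the list alone (median 0.33, camera adjusted p = 0.00103, but adjusted p = 0.769 with an estimated correlation). Hypoxia and glycolysis genes rose in 11 of 15 cases and fell in 3, the same when adjusted over the list alone (median 0.28, camera adjusted p = 0.0107, but adjusted p = 0.769 with an estimated correlation), with Slc2a1 1.67-fold higher. Of 6 histone genes 5 rose and 0 fell, the same when adjusted over the list alone (median 0.79, camera adjusted p = 0.0106, but adjusted p = 0.0977 with an estimated correlation).

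Whether mifepristone altered the response to NaCl was tested as an interaction, the log2 effect of NaCl in mifepristone cells minus that in vehicle cells. Fxyd2 had the most negative interaction of the named genes (-4.25, SE 0.078): NaCl raised it by 7.64 on the log2 scale in vehicle cells and 10.5-fold in mifepristone cells, where voom gave a log2 fold change of 6.96. Nr1h4 (-2.80, SE 0.1) rose with NaCl in vehicle cells and fell in mifepristone cells, from 4.37 ± 0.237 to 1.70 ± 0.144 FPKM (SD, n = 3 per group). Saa3 (-2.80, SE 0.264), the epidermal factor gene Zfp750 (-2.68, SE 0.115) and the calcium-binding protein gene S100g (-2.61, SE 0.306) were also lower. Ppbp had the most positive interaction (4.40, SE 0.133), with 2.35 ± 0.0587 FPKM in mifepristone and 96.8 ± 2.05 FPKM in mifepristone plus NaCl libraries (SD, n = 3 each). In all, limma called an interaction in 4374 of 14044 genes, 1915 positive and 2459 negative, of which 148 and 118 reached 1 on the log2 scale. The excess of negative interactions depended on scaling, with 2255 positive and 2149 negative under median-ratio scaling and 2366 and 2410 under quantile normalization.

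The positive interactions of S100b (2.87, SE 0.132) and of Loxl4, a lysyl oxidase gene of matrix crosslinking (2.63, SE 0.139), were also large. The positive interactions of Ccl7 (2.73, SE 0.246), Alox12e (2.32, SE 0.067), Slc6a12 (1.09, SE 0.085) and Umod (1.38, SE 0.11) rest on the scale log2(FPKM + 0.5), since these genes were near 0 FPKM in at least 1 group. With voom on the recovered reads they were 0.41, -0.24, -0.16 and 0.37. Slc5a3 (-0.88, SE 0.13) and Kif12 (-0.36, SE 0.083) had negative interactions. Akr1b3 (-0.24, SE 0.117), Nfat5 (-0.19, SE 0.233), Slc6a6 (0.25, SE 0.147), Slc14a2 (0.20, SE 0.115), Pkd2 (-0.16, SE 0.077) and Pkhd1 (-0.06, SE 0.26) did not pass. Without mifepristone C those of Nfat5 (-0.41) and Pkd2 (-0.23) passed, as they did with library quality weights (-0.39 and -0.20), and that of Akr1b3 passed under quantile normalization and with these weights (-0.28 each). That of Pkd2 also passed with length-corrected values (limma adjusted p 0.00288), at an unchanged -0.16 and a spread narrowed by the correction. Those of Pkd2 (-0.21) and Akr1b3 (-0.22) passed without vehicle A and mifepristone C. With voom the interactions of S100b and Zfp750 were 4.41 and -5.51.

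Mesenchymal and matrix genes had positive interactions in 7 of 13 cases and a negative one in 1, or 7 and 2 when adjusted over the list alone (median 0.53, camera adjusted p = 0.00478, but adjusted p = 0.101 with an estimated correlation). Without the expression filter the list was not called (adjusted p = 0.114). The basement membrane collagen gene Col4a1 (2.01, SE 0.091), Cyr61 (1.28, SE 0.082), Ctgf (1.26, SE 0.107) and Cdh2 (1.04, SE 0.059) were positive. Osmotic response genes had 7 positive and 4 negative interactions of 17, 8 and 5 when adjusted over the list alone, and were not called as a list (median 0.25, camera adjusted p = 0.132). Genes tied to the mutated factor had 2 positive and 7 negative of 18, 3 and 8 when adjusted over the list alone, and were not called either (median -0.17, camera adjusted p = 0.132). Across the 14044 genes the NaCl effects without and with mifepristone were correlated (Pearson r 0.734, Spearman rho 0.643), with 2173 genes higher in both against 867 for independent lists and 3004 lower in both against 1515. Of 4007 genes raised by NaCl on average, 45.1% were raised less with mifepristone, and of 5427 lowered genes 47.3% were lowered less. The number of genes with an interaction of mifepristone and NaCl depended on mifepristone C, and was 6784 without it. With library quality weights it was 7156, at an adjusted p under 0.01 it was 2618, and among genes of mean FPKM of at least 5 it was 2807. The share of lowered genes lowered less was 50.6% without vehicle C, and the share of raised genes raised less was 51.0% among genes of mean FPKM of at least 5.

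Whether genes that changed with mifepristone lie near ChIP peaks was tested with the authors' mark of a nearby peak, which 3987 of the 14044 tested genes carried (28.4%). The p-values and intervals of these tests treat genes as independent, which they are not, and do not measure the spread between libraries. Of the 327 genes lowered at least 2-fold without NaCl, 206 carried the mark (63%, odds ratio against the other tested genes 4.47, 95% interval 3.54 to 5.67, Fisher's exact test, two-sided, adjusted p = 1.39e-38). Of the 353 lowered at least 2-fold with NaCl, 229 did (64.9%, odds ratio 4.88, interval 3.89 to 6.14). Kif12, Cdkl1, Tspan8, Cdh6 and Sult1c2 led the marked genes that fell. Genes raised at least 2-fold without NaCl carried the mark in 38.2% of cases (odds ratio 1.59, interval 1.33 to 1.89), led by Slpi, Prune2, Chst1, the matrix gene Dcn (10.7-fold higher) and the kinase gene Pkdcc (10.3-fold higher). Genes changed at least 2-fold by NaCl in vehicle cells carried it too, 51.1% of the 180 lowered (odds ratio 2.68, interval 1.97 to 3.635) and 47.7% of the 384 raised (odds ratio 2.36, interval 1.91 to 2.91).

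Among all 4421 genes lower with mifepristone without NaCl the mark was carried by 31.1%, against 27.1% of the others (odds ratio 1.21, Fisher's exact adjusted p = 2.15e-06), and among all 3970 higher genes by 33.7%, against 26.3% of the others (odds ratio 1.425, adjusted p = 1.31e-17). With NaCl the order was the other way, 35.7% of the lower genes (odds ratio 1.67, adjusted p = 9.92e-38) and 29.7% of the higher genes (odds ratio 1.09, adjusted p = 0.0432). Without mifepristone C the odds ratio of the lower genes without NaCl was 1.05 (Fisher's exact p = 0.254), while the odds ratio of a nearby ChIP peak among genes at least 2-fold lower with mifepristone was 4.22. The peaks, their tissue and the distance behind the mark are not given in the sources used here.

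**Figure D3:**
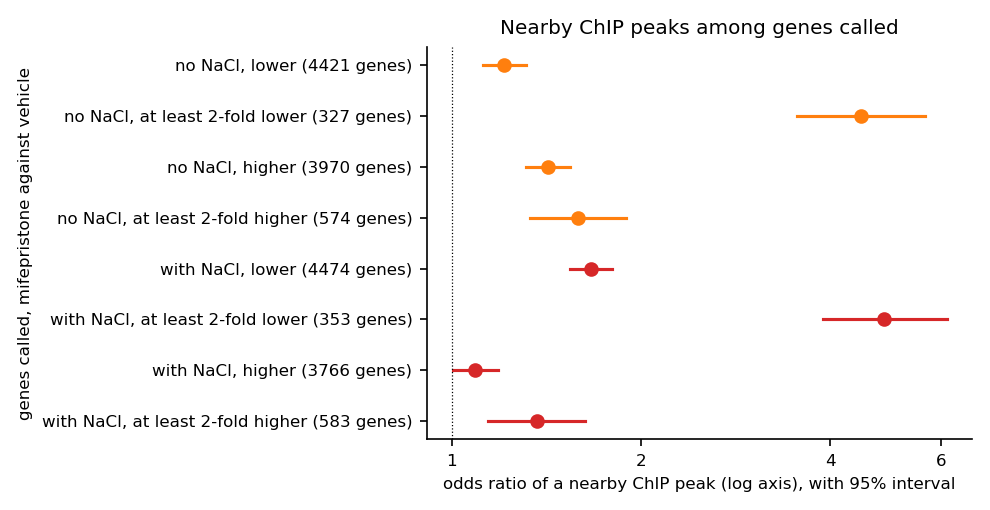
Odds ratio (horizontal log axis, points with 95% intervals) of a nearby ChIP peak among genes called with mifepristone against the other tested genes, without NaCl (orange) and with NaCl (red). The dotted line marks an odds ratio of 1. The intervals treat genes as independent, which they are not. Genes lowered at least 2-fold have the highest ratios, 4.47 and 4.88.

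The authors' deposited table of mifepristone against vehicle without NaCl listed 908 genes at an adjusted p under 0.05, 596 higher and 312 lower. Of these, 691 were tested here and each of the 691 was also called here in the same direction. In the authors' deposited table of NaCl effects 9171 genes passed in vehicle cells and 10252 in mifepristone cells. The authors' deposited table gave 88 genes an interaction at an adjusted p under 0.05, 55 positive and 33 negative, with a smallest absolute log2 value of 1.32. No absolute log2 value under 1.07 in the mifepristone table or under 1.21 for the interaction had an adjusted p below 1, so the 908 and 88 genes are not counts of the same test as the 8391 and 4374 here. The log2 fold changes computed here had the same sign as those in the authors' deposited tables for 98.4% to 99.6% of shared genes. Both rest on the same reads, so this compares methods, not samples.

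Markers of other cell types were mostly unmeasured. Of 8 endothelial markers 0 passed the filter, of 10 fibroblast markers 1 (Dcn) and of 9 immune cell markers 2. With mifepristone without NaCl the immune markers went both ways, Csf1r 3.83-fold lower and Cd68 1.26-fold higher. Of 15 proximal tubule markers 3 were measured, and Ass1 rose while Aqp1 and the endocytic receptor gene Lrp2 (2.4-fold) fell, so that their median was -1.26 and their mean 0.21. Of 10 thick ascending limb and distal tubule markers Umod fell and the magnesium channel gene Trpm6 rose 2.39-fold. Of 10 intercalated cell markers Car2 fell 3.8-fold and the anion exchanger gene Slc26a4 rose 1.75-fold. With voom the log2 fold changes of Dcn, Lrp2 and Slc26a4 were 6.16, -2.56 and 3.11.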

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

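The tests of the transcript length trend, of mixing, and of length and scaling behind the cholesterol genes, and voom, were chosen only after the result was seen.

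These results drew attention because the effect of NaCl differed between mifepristone and vehicle cells, by the limma interaction test. The interactions (log2) were -4.25 for Fxyd2, -2.80 for Nr1h4, -2.80 for Saa3, -2.68 for Zfp750, -2.61 for S100g, -0.88 for Slc5a3 and -0.36 for Kif12. They were 4.40 for Ppbp, 2.87 for S100b, 2.73 for Ccl7, 2.63 for Loxl4, 2.32 for Alox12e, 1.38 for Umod and 1.09 for Slc6a12, and the median over mesenchymal and matrix genes was 0.53. With voom on the recovered reads, those of Ccl7 (0.41), Alox12e (-0.24), Umod (0.37) and Slc6a12 (-0.16) did not pass. Saa3 was near 0 FPKM in both vehicle groups, and Fxyd2 in vehicle cells without NaCl, so the sizes of their interactions depend on the added 0.5.

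Other splits of the same libraries were counted. For the 4 treatment comparisons 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 8391, 8240, 7965 and 8248 genes, in each case 1 of 10 splits reached its count, and the highest other split gave 0. For the interaction, 2 of 100 splits within the salt levels, the real one included, gave at least the real 4374 genes. The highest other split gave 9538 genes, and it exchanges all vehicle and mifepristone labels among the NaCl libraries, which turns the interaction into the mifepristone effect, a structure of the samples. The 75 splits that mix vehicle and mifepristone libraries at both salt levels gave 0 genes and the 23 that mix them at 1 level up to 3971. The mifepristone effect thus enters these counts, so they are no measure of chance for the interaction.

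Vehicle A and mifepristone C deviated from their groups along transcript length, with Spearman rho across genes of -0.44 and -0.51 against exon length, and the other libraries had trends of either sign, up to 0.46 in mifepristone A. A length trend between libraries, of RNA quality or of library preparation, is a candidate explanation, but these values restate the observation and do not test it. Vehicle RNA mixed into mifepristone C would raise the genes that mifepristone lowers, and over 331 genes lowered at least 2-fold in mifepristone A and B its median log2 difference from them was 0.019 (quartiles -0.09 and 0.16). Over 613 genes raised at least 2-fold it was -0.109 (quartiles -0.28 and 0.08), the direction that mixing predicts. Choosing the genes by A and B favours that direction without any mixing, and the values together decide neither way. No biological explanation was tested, since the design gives none within a group.

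Among genes raised at least 2-fold by NaCl on average, 172 with a nearby ChIP peak had a median interaction of 0.05 and 203 without had 0.24, a difference of -0.20 (permutation test over genes, two-sided, p = 0.00894, though genes are not independent). Neither set was raised less by NaCl with mifepristone, as both medians lie above 0, and 45.3% and 39.9% of the genes were. Library mifepristone C is argued against as the whole cause, since the difference was -0.22 without it. Averaged over 4 bins of mean expression over all 12 libraries the difference was -0.18, but the bins ran from -0.51 to 0.04. Such bins do not separate genes near 0 FPKM without NaCl, whose interactions depend on the added 0.5. The difference was not computed with voom or another pseudocount, so an effect of expression level stays open. What a nearby peak stands for in this difference was not tested, as the peaks were not measured in these libraries, and genes lowered at least 2-fold by NaCl in vehicle cells carried the mark too (odds ratio 2.68).

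Cholesterol synthesis genes fell with mifepristone and with NaCl, and the average effects of the treatments had list medians of -0.89 and -0.51. Both averages use the same 12 libraries, and their chance parts are uncorrelated only if all groups have equal spread. A transcript length trend is argued against as the whole cause, since with the trend of the log2 fold changes on exon length removed the medians without the other treatment were -0.945 and -0.495. Scaling by 1 factor per library shifts all genes alike and is argued against too, since the medians of all genes were -0.011 and -0.024. Under quantile normalization the list medians minus those of all genes were -0.89 and -0.47. That subtraction removes a shift of all genes by construction, so these 2 values do not test such a factor. A nearby peak was marked for 9 of 24 list genes (37.5%) against 28.4% of the other genes (Fisher's exact test, two-sided, p = 0.365, odds ratio 1.51, 95% interval 0.58 to 3.7). Whether binding near these genes may contribute stays open, as 24 genes are too few.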

How the results depend on the processing

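Voom on the recovered reads, length-corrected values (trends within groups), and leaving out vehicle A and mifepristone C together were chosen only after the result was seen. Length-corrected values leave fold changes as they were, so calls gained with them follow from a narrowed spread within groups. Where no cause is named below, the cause was not tested. Over all alternatives 13971 values of named genes kept their direction and side of the threshold, 140 lost their call, 28 gained one and 3 turned, and 693 tests of the lists called kept theirs while 25 lost it. Tests of lists not called are outside this count.

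The pseudocount shifts the fold of low genes by construction. With 0.1 the at least 2-fold lower genes with NaCl numbered 306 in vehicle and 389 in mifepristone cells, and with 1 they numbered 115 in vehicle cells, with 97 positive and 76 negative interactions of that size. Voom gave 398 and 437 lower genes with NaCl and 231 positive interactions, a share of raised genes raised less of 40.0%, a turned share of lowered genes lowered less of 53.8%, and turned interactions of Slc6a12 (-0.16), Alox12e (-0.24) and Axin2 (-0.62).

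Without a filter the share raised less was 35.7% and 4 lists had an interaction. A mean FPKM of at least 5, which tests fewer genes, gave 5414 genes for mifepristone with NaCl and 2807 interactions. At least 2-fold higher and lower were then 324 and 157 genes (mifepristone without NaCl), 304 and 187 (mifepristone with NaCl), 219 and 85 (NaCl in vehicle), 235 and 124 (NaCl with mifepristone), and 52 and 54 (interaction), with a turned share raised less of 51.0% and a correlation of NaCl effects of 0.789. Quantile normalization called 10 lists with NaCl in vehicle cells and 2 interaction lists, and median-ratio scaling turned the share lowered less to 51.1%. Library weights gave 7156 interactions, with 182 at least 2-fold negative, and the stricter adjusted p under 0.01 gave 2618. With an estimated correlation the lists called were 2 and 2 (mifepristone without and with NaCl), 3 and 1 (NaCl in vehicle and mifepristone cells) and 0 (interaction), against 8, 8, 6, 7 and 1.

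Leaving out each library in turn gave 3512 to 6784 genes with an interaction of mifepristone and NaCl and 99 to 193 at least 2-fold negative ones, both highest without mifepristone C. The share lowered less ran from 44.2% to 50.6%, turned without vehicle C. The correlation of NaCl effects ran from 0.681 (without mifepristone C) to 0.755, and the odds ratio of a nearby ChIP peak among genes lower with mifepristone from 1.046 (without mifepristone C, where its call was lost) to 1.338. Deviations of libraries with equal letters correlated from -0.5 to 0.288 over 18 pairs, with 6 pairs over 0.1. Length trends of the libraries enter these values, so they show no clear pairing but do not exclude a shared culture or day. Count models other than voom and a stricter peak mark were not run, the latter because the table gives no score or distance.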

Other observations

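The steroid receptor test was chosen only after the result was seen.

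The lists in this paragraph were not called with mifepristone without NaCl. Of 7 measured genes of collecting duct principal cells 5 rose and 2 fell, the same when adjusted over the list alone (median 0.29, camera adjusted p = 0.141). Hsd11b2, which inactivates glucocorticoids, rose 4.07-fold and the sodium channel gene Scnn1a 2.39-fold. Of 8 Wnt target genes 4 rose and 3 fell, the same when adjusted over the list alone (median 0.34, camera adjusted p = 0.577), with Lef1 3.16-fold higher (but a log2 fold change of 2.79 with voom on the recovered reads) and Myc 2.36-fold lower. Among p53 target genes 7 of 18 rose and 7 fell, the same when adjusted over the list alone (median -0.05, camera adjusted p = 0.995), with the cell cycle inhibitor gene Cdkn1a 2.09-fold lower. Psat1, an enzyme of serine synthesis, rose 4.1-fold, and the co-chaperone gene Bag3 2.78-fold. Of 13 mitochondrially encoded genes 1 rose and 0 fell, the same when adjusted over the list alone (median 0.06, camera adjusted p = 0.577).

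NaCl raised Atp1b1, the beta subunit of Na,K-ATPase, 4.18-fold in vehicle cells, and its interaction was negative (-0.41, SE 0.054). The NRF2 target genes Srxn1 (1.91-fold) and Nqo1 (3.03-fold, but a log2 fold change of 4.37 with voom on the recovered reads) rose with NaCl in vehicle cells while Gsr fell 1.84-fold, and the list was not called (camera adjusted p = 0.614).

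A hypothesis that mifepristone and NaCl move the same genes the same way was tested on the average effect of each treatment. Both averages use the same 12 libraries, so their chance parts are uncorrelated only if all groups have equal spread. Pearson r across the 14044 genes was 0.125 and Spearman rho 0.175, too low or too high to decide by the bounds set, and genes are not independent replicates.

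Mifepristone also binds steroid receptors, and its own action may account for part of the changes. Over 10 steroid receptor target genes without NaCl 4 rose and 3 fell, 4 and 4 when adjusted over the list alone (median -0.03, camera adjusted p = 0.995), with Klf9 2.58-fold higher and Mt2 6.44-fold lower. Members that go both ways decide nothing, and no cells without the inducible mutant are among the 12 libraries. The action of mifepristone itself and that of the mutant thus cannot be told apart for any gene here.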
